A study of Arabidopsis thaliana with 16 samples.

How the data were processed

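Total RNA of roots was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols, in 16 samples of Arabidopsis thaliana, 4 each of control, potassium, sulfur and iron limitation. The deposited values are on a log2 scale and were made with RMA, per the submitters' processing notes, a method that corrects background, makes the distributions of all arrays equal and summarises the probes of each probe set. The RMA software version, the array design and the definition of the probe sets are not given in the sources used here. The values of all 16 arrays had the same distribution, with a median of 5.62 in each and medians that differed by at most 0.000244. This normalization assumes that most genes do not change, so an overall shift in RNA content between groups cannot be seen in these data, and RMA compresses differences near the low end of the scale. No detection calls were used, since the table holds none, and a low value is a level near background, not an absent transcript. Array data have no read depth, and the number of arrays limits the precision.

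The table held 27826 probe sets, each named by an Arabidopsis locus, with 1 probe set per locus, no control probe sets and no missing values. Of these, 27241 loci matched a gene table of assembly TAIR10.1, which was used for names alone, and 585 did not and keep their locus names. Which loci share probes with near-identical genes is not given in the sources used here.

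Groups came from the nutrient limitation given in the labels. A linear model with 1 mean per group was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), so that the groups shared 1 estimate of the spread with 12 residual degrees of freedom. Each limitation was compared with the control and with the other limitations. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all 27826 probe sets, and calls of at least 2-fold were counted apart. All p-values for single genes are adjusted p-values of this limma test, two-sided. Fold changes are on the RMA scale, and those from or to levels below the array median may be compressed, also where the text does not repeat this.

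Before the data were examined, 24 gene lists with 367 loci were fixed from general knowledge, of which 366 loci were measured. Each list was tested with limma's camera, which compares the members with the other probe sets, at a preset inter-gene correlation of 0.01, and adjusted over the 72 tests of lists against control. Of these 26 passed, and 6 also passed with a correlation estimated from the residuals. These 6 were the hypoxia list under potassium limitation, the sulfur deficiency, potassium, nitrogen and phosphate lists under sulfur limitation, and the iron uptake and deficiency regulon under iron limitation. Camera tests of the lists between limitations, adjusted apart over as many tests, were added after seeing the data. Members were also counted with the adjustment over the list alone.

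The genes named in the text were fixed by a rule. Per limitation it took the 8 largest rises and the 8 largest falls among called probe sets whose 4 limited and 4 control arrays did not overlap, up to 4 members with the smallest adjusted p of each list that passed or was made for the nutrient, and 14 marker genes whatever their values. It also took the 5 probe sets called in the same direction in all 3 limitations with the largest smallest change, and the 3 called in opposite directions for each pair of limitations. Genes named outside the rule are marked in the text as chosen after their values were seen.

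Overlaps of calls were set beside the number for independent lists, 100 simulations in which unchanged groups drawn from the residuals shared the controls, and the 6 ways of splitting the controls 2 and 2. The limma test was tested on simulated data with the levels and spreads of the 27826 probe sets, for the comparison of potassium limitation with control. It called 92% of the probe sets changed by 1 on the log2 scale and 99% of those changed by 2, and 2.05% of its calls were false. The simulated noise was independent between probe sets, and few probe sets were changed, so these rates need not hold for the measured data.

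The alternatives were quantile normalization again, centring each array on its median, only probe sets above the median level, only loci in the gene table, only the 8 arrays compared, eBayes with trend and robust, array weights, no variance moderation, the replicate number as a block, and leaving out each array in turn. No batch, scan date or harvest time is given in the labels used here, so none was tested. Nothing else was left out, and all 16 arrays entered every main comparison.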

Results

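Transcript levels were measured in roots of Arabidopsis thaliana Columbia-0, the reference wild type, grown hydroponically for 7 weeks with 8 h of light and 16 h of darkness. The 16 samples formed 4 groups of 4, a control with full nutrients and plants limited in potassium, sulfur or iron, and the labels call the 4 samples of each group biological replicates. Sulfur and iron were limited for the last 5 weeks after 2 weeks of full supply. Potassium was lowered from 3 mM to 0.3 mM during the first 2 weeks and left out for the following 5 weeks, so this group also differed from the control in its early potassium supply. Each array gave 27826 log2 levels, and the number of arrays limits the precision of every value. The comparisons address how roots adjust their transcripts to a shortage of each nutrient. Correlations between arrays ran from 0.988 to 0.995 within groups and from 0.958 to 0.991 between groups. The leading principal component held 41.8% of the variance and set the iron limited roots apart. A further 25.7% set the sulfur limited roots apart, and 6.48% separated the potassium limited roots from the control.

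**Figure D1:**
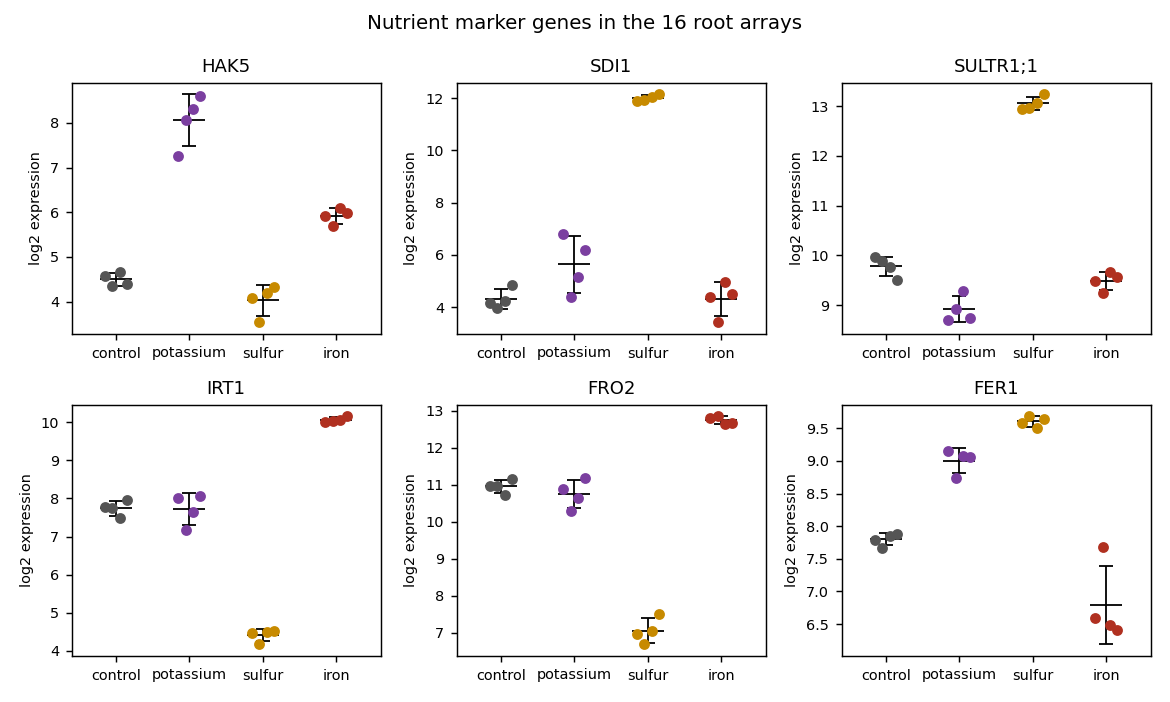
Log2 expression of 6 nutrient marker genes (vertical axes) in the 4 arrays of each group (horizontal axes), with 1 point per array and the mean ± SD as bars. HAK5 is highest under potassium limitation (mean 8.06), SDI1 and SULTR1;1 under sulfur limitation (12.01 and 13.05), and IRT1 and FRO2 are lowest under sulfur limitation (4.41 and 7.06) and highest under iron limitation (10.06 and 12.75).

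Under potassium limitation the high-affinity potassium transporter gene HAK5 (AT4G13420) rose from 4.50 ± 0.15 to 8.06 ± 0.58 log2 units (SD, n = 4), which is 11.9-fold (limma adjusted p = 5.26e-07). Genes of the hypoxia response, which are induced when oxygen is short and carry fermentation and oxygen sensing, fell together: 11 of the 12 measured members were lower, and 12 when adjusted over the list alone. ADH1 (AT1G77120), encoding alcohol dehydrogenase, fell from 12.19 ± 0.79 to 8.46 ± 0.72 log2 units (n = 4, limma adjusted p = 8.09e-05). PDC1 (AT4G33070), encoding pyruvate decarboxylase, was lower by a log2 change of -3.79, and the desaturase gene SAD6 (AT1G43800) and the cysteine oxidase gene PCO2 (AT5G39890) were 8.71-fold and 8.26-fold lower. The list had a median log2 change of -2.23 and a camera adjusted p = 2.56e-28, or an adjusted p = 0.0208 with an estimated correlation.

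The largest falls also included NIP2;1 (AT2G34390), a channel protein gene, with a log2 change of -4.59 ± 0.56 (SE), and AT1G67865 and AT4G33560, with -2.68 and -2.55. AT5G10040 had a log2 change of -3.64 (limma adjusted p = 0.0297), a call that was lost without control replicate 2, 3 or 4 and without any 1 of the potassium replicates (adjusted p up to 0.0979), and with eBayes with trend and robust (0.0541). Among the largest rises were the myrosinase genes TGG1 (AT5G26000) and TGG2 (AT5G25980), which encode enzymes that hydrolyse glucosinolates, at 4.98-fold and 5.59-fold. The beta-amylase gene CT-BMY (AT4G17090) was 4.28-fold higher, and AT5G52700, AT1G78230 and AT3G28510 had log2 changes of 2.07, 2.04 and 1.98. RBCS1A (AT1G67090), a gene of the Rubisco small subunit, was 4.95-fold higher (limma adjusted p = 0.00836). It was the 1 member called among 11 green tissue markers, 6 when adjusted over the list alone, and that list as a whole lay higher (camera adjusted p = 0.000653, or adjusted p = 0.258 with an estimated correlation). In potassium replicate 1 the mean of that list was 0.077 relative to the control mean, within the control arrays (-0.351 to 0.304). In potassium replicates 2 to 4 it was 0.971, 0.863 and 0.567. The cause of the higher level of the green tissue markers was not tested, so it cannot be read as a response of root cells.

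Of 34 genes of potassium transport and its regulation, 4 rose and none fell, and 5 were higher and 1 lower when adjusted over the list alone. They were HAK5, the protein kinase gene CIPK23 (AT1G30270, log2 change 0.37 ± 0.07 SE), the calcium sensor gene CBL1 (AT4G17615, 1.35 ± 0.30) and the cation exchanger gene CHX17 (AT4G23700, 1.68 ± 0.38). The calls of CBL1 and CHX17 were lost without control replicate 1 or potassium replicate 4, without potassium replicate 3, and for CBL1 also without potassium replicate 2 (adjusted p up to 0.0614 and 0.057), and with the 8 arrays of the comparison alone (0.0782 and 0.075). The channel genes AKT1 and SKOR and the carrier gene KUP3 had log2 changes of 0.16, -0.04 and -0.03, with limma adjusted p = 0.296, 0.906 and 0.929. The list test gave a camera adjusted p = 0.287, with a median of -0.02 and a mean of 0.19, which differ in sign.

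Genes of iron storage and vacuolar sequestration lay higher as a list, with 3 of 11 members called, and 4 when adjusted over the list alone (camera adjusted p = 3.29e-05, or adjusted p = 0.0672 with an estimated correlation). The ferritin gene FER1 (AT5G01600) rose 2.31-fold and the vacuolar iron transporter-like gene VTL5 (AT3G25190) 2.33-fold. In the iron uptake and deficiency regulon 7 of 40 members were lower and 1 was higher, against 8 and 3 adjusted over the list alone, with a camera adjusted p = 0.068. BHLH100 (AT2G41240), a transcription factor gene of that regulon, had a log2 change of -1.50. BHLH39 had -0.84 (limma adjusted p = 0.023), a call lost without control replicate 2 or 4 or potassium replicate 2 or 3 (adjusted p up to 0.0771), or with the 8 arrays alone (0.0543). IRT1, FRO2 and FIT had log2 changes of -0.02, -0.20 and -0.06, none past the threshold. The sulfate transporter gene SULTR1;1 fell 1.82-fold, while SULTR1;2, APR3, SDI1 and LSU1 had log2 changes of 0.19, 0.54, 1.33 and -0.06, none past the threshold. Of 34 genes of sulfate transport and assimilation 1 was higher and 4 were lower, against 2 and 4 adjusted over the list alone (camera adjusted p = 0.859), with a median just under 0 and a mean of 0.02, which differ in sign. In the list of 23 jasmonate genes JAZ6 (AT1G72450) was the 1 member called, with a log2 change of 1.07, and 6 were higher when adjusted over the list alone (camera adjusted p = 0.000346, or adjusted p = 0.278 with an estimated correlation). The mean of the jasmonate list in potassium replicate 1 was -0.052 relative to the control mean, within the control arrays (-0.323 to 0.166). In potassium replicates 2 to 4 it was 0.498, 0.364 and 0.742. The nitrate transporter gene NRT2.1 (AT1G08090) fell 4.59-fold and was the 1 member called among 20 nitrogen genes, against 1 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.162).

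Salicylate and defence genes had 2 of 11 members higher, 3 adjusted over the list alone, with the isochorismate synthase gene ICS1 (AT1G74710) 1.84-fold higher (camera adjusted p = 0.0237, or adjusted p = 0.125 with an estimated correlation). Without potassium replicate 3 that list had an adjusted p = 0.0519. Its other called member, WRKY70 (AT3G56400), lost its call without control replicate 1, 3 or 4 or potassium replicate 2, 3 or 4 (limma adjusted p up to 0.111). With the 8 arrays alone WRKY70 had a limma adjusted p = 0.0747. Zinc and copper genes had 2 of 15 higher and 1 lower, against 7 and 2 adjusted over the list alone, with ZIP3 (AT2G32270) at 0.60 and ZIP2 (AT5G59520) at -0.75 on the log2 scale (camera adjusted p = 0.0231, or adjusted p = 0.0835 with an estimated correlation). The call of this list was lost without control replicate 4 (adjusted p = 0.0501) and without potassium replicate 4 (adjusted p = 0.0549). Its other higher member, MTP1 (AT2G46800, log2 change 0.38), lost its call without any 1 of the 8 arrays (limma adjusted p up to 0.125). With eBayes with trend and robust MTP1 had a limma adjusted p = 0.062. Endodermis and suberin markers had 1 of 14 higher, 5 adjusted over the list alone (camera adjusted p = 0.0114, or adjusted p = 0.239 with an estimated correlation). That member, CASP2, had a log2 change of 0.75 (limma adjusted p = 0.0371) and lost its call without any 1 of the 8 arrays (adjusted p up to 0.0917).

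In all, 1080 of 27826 probe sets were called under potassium limitation at a limma adjusted p under 0.05, 503 higher and 577 lower, with 73 and 104 of them at least 2-fold. The number called was 685 without control replicate 3, 681 without potassium replicate 4, and 1732 with array weights.

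**Figure D2:**
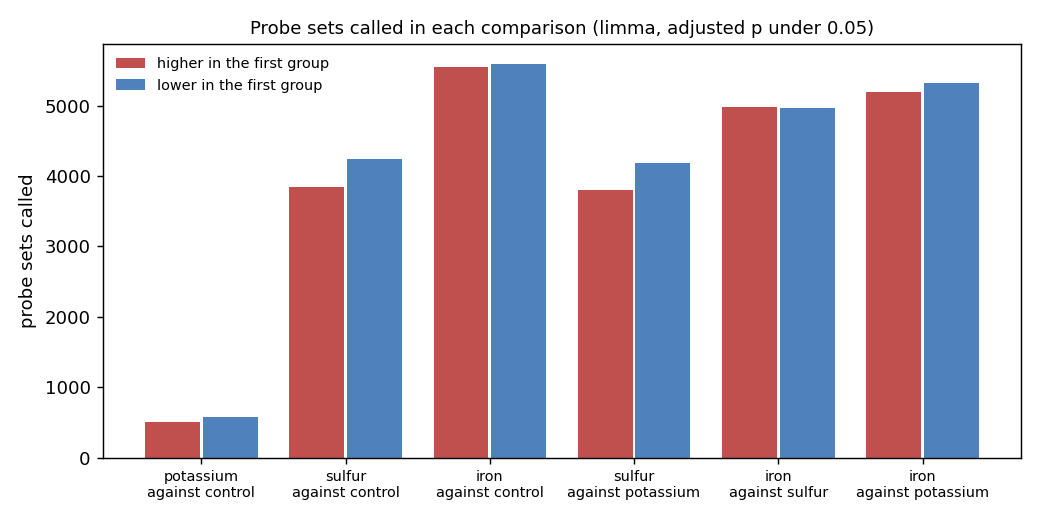
Number of probe sets called higher and lower (vertical axis) in each of the 6 comparisons (horizontal axis), with 1 bar per direction. Potassium limitation against control has 503 and 577, and the other 5 comparisons have between 3796 and 5591 in each direction.

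Under sulfur limitation all 12 measured sulfur deficiency markers rose, and all 12 when adjusted over the list alone. SDI1 (AT5G48850), a repressor of glucosinolate synthesis, went from 4.30 ± 0.39 to 12.01 ± 0.11 log2 units (SD, n = 4), which is 209.5-fold (limma adjusted p = 3.63e-09). LSU1 (AT3G49580) and LSU3 (AT3G49570) rose 77.8-fold and 55.2-fold, the beta-glucosidase gene BGLU28 (AT2G44460) 84.5-fold, and GGCT2;1 (AT5G26220), which acts in glutathione breakdown, 77.2-fold. The control mean of LSU1 was 2.17 log2 units, far below the array median of 5.62, where RMA compresses differences. Its fold change is therefore not exact. That of SDI1, with a control mean of 4.30, also starts below this median. The list had a median log2 change of 4.51 (camera adjusted p = 8.21e-22, or adjusted p = 0.00599 with an estimated correlation). Also among the 8 largest rises were AT1G12030, AT3G55790, BCA3 (AT1G23730) and AT3G05400, with log2 changes between 5.90 and 6.86.

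Sulfate transport and assimilation had 15 of 34 genes higher and 4 lower, against 16 and 4 adjusted over the list alone (camera adjusted p = 8.66e-05, or adjusted p = 0.0672 with an estimated correlation). The root sulfate uptake transporter gene SULTR1;1 (AT4G08620) rose from 9.78 ± 0.20 to 13.05 ± 0.13 log2 units (n = 4, limma adjusted p = 1.23e-10) and SULTR1;2 (AT1G78000) from 11.23 ± 0.09 to 12.37 ± 0.08. SULTR2;1 (AT5G10180) rose 12.8-fold, the adenylyl sulfate reductase gene APR3 (AT4G21990) 10.4-fold, and the serine acetyltransferase gene SERAT3;1 (AT2G17640) 4.93-fold. Its relative SERAT3;2 (AT4G35640) rose from 3.41 ± 0.15 to 7.41 ± 0.25 log2 units. Glucosinolate synthesis genes went both ways, 5 of 29 higher and 11 lower, against 6 and 12 adjusted over the list alone (camera adjusted p = 0.17). CYP79B3 (AT2G22330), which starts the indole branch, fell 2.49-fold, while MYB122 (AT1G74080) and the sulfotransferase gene SOT16 (AT1G74100) rose 1.91-fold and 1.60-fold.

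Of 40 genes of the iron uptake and deficiency regulon, 23 fell and 4 rose under sulfur limitation, against 27 and 4 adjusted over the list alone. The ferric chelate reductase gene FRO2 (AT1G01580) fell from 10.96 ± 0.18 to 7.06 ± 0.35 log2 units (SD, n = 4, limma adjusted p = 6.28e-10). The iron transporter gene IRT1 (AT4G19690) fell 10.1-fold, the coumarin hydroxylase gene S8H (AT3G12900) 11.96-fold and the copper transporter gene COPT2 (AT3G46900) 5.33-fold. The regulator FIT (AT2G28160) was 1.35-fold lower (limma adjusted p = 0.0188), with an adjusted p = 0.0639 without control replicate 1. BHLH39 had a log2 change of -0.06 (limma adjusted p = 0.862). The members that rose were IMA1 and IMA2, which encode peptides that promote iron uptake, by 1.60 and 2.03 on the log2 scale, and F6'H1 and NRAMP1, by 0.38 and 0.38, chosen after their values were seen. The list had a camera adjusted p = 1.48e-07, or an adjusted p = 0.102 with an estimated correlation. FER1 and VTL5 had log2 changes of 1.81 and -1.63 in the iron storage list, whose test was not past the threshold (1 of 11 higher and 3 lower, also when adjusted over the list alone, camera adjusted p = 0.732).

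Of 34 genes of potassium transport and its regulation 17 fell and 3 rose, the same numbers as adjusted over the list alone (camera adjusted p = 0.000154, or adjusted p = 0.0384 with an estimated correlation). SKOR (AT3G02850), a channel gene for potassium release into the xylem, fell from 10.32 ± 0.06 to 7.91 ± 0.12 log2 units (n = 4, limma adjusted p = 1.08e-09). CBL9 (AT5G47100), KUP9 (AT4G19960), CIPK23 and AKT1 had log2 changes of -1.30, -0.89, -0.73 and -0.30, while HAK5 had -0.47 and KUP3 -0.16, neither past the threshold. Nitrogen genes had 10 of 20 lower and 3 higher, with the same numbers adjusted over the list alone (camera adjusted p = 0.00157, or adjusted p = 0.0384 with an estimated correlation). The nitrate transceptor gene NRT1.1 (AT1G12110) fell 6.28-fold, the nitrate reductase gene NIA1 (AT1G77760) 3.75-fold and the glutamine synthetase gene GLN1;2 (AT1G66200) 2.13-fold. Phosphate starvation genes had 7 of 14 lower and none higher, 8 lower adjusted over the list alone, with PHO1;H1 (AT1G68740) at a log2 change of -2.34 (camera adjusted p = 0.00235, or adjusted p = 0.0384 with an estimated correlation). The molybdate transporter gene MOT1 (AT2G25680) was 11.6-fold lower and the cell wall protein gene CWLP (AT3G22120) 14.6-fold lower.

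Hypoxia response genes fell here too, 10 of 12, with 10 also adjusted over the list alone (median log2 change -2.04, camera adjusted p = 2.63e-08, or adjusted p = 0.183 with an estimated correlation). ADH1 fell 15.3-fold, SAD6 11.3-fold, SUS4 (AT3G43190), a sucrose synthase gene, 7.73-fold and the haemoglobin gene HB1 (AT2G16060) 4.29-fold. NIP2;1 fell by 4.66 on the log2 scale, and AT5G10040 had a log2 change of -3.96. Carbon starvation genes had 7 of 9 members lower, 7 also adjusted over the list alone, with SEN1 (AT4G35770) and DIN10 (AT5G20250) 5.22-fold and 2.48-fold lower (camera adjusted p = 0.000912, or adjusted p = 0.278 with an estimated correlation). Cell division genes had 8 of 10 lower, 8 also adjusted over the list alone, among them CYCB2;4 (AT1G76310), MCM5 (AT2G07690), MCM2 (AT1G44900) and KNOLLE (AT1G08560), with log2 changes from -0.72 to -1.13 (camera adjusted p = 5.72e-06, or adjusted p = 0.0743 with an estimated correlation). Xylem secondary wall markers had 3 of 6 lower, 3 also adjusted over the list alone, with XCP1 (AT4G35350) and the cellulose synthase gene CESA4 (AT5G44030) at -0.47 and -0.47 (camera adjusted p = 0.0298, or adjusted p = 0.258 with an estimated correlation). Among probe sets above the median level, that list had an adjusted p = 0.113. In all, 8082 probe sets were called, 3844 higher and 4238 lower, with 493 and 498 at least 2-fold.

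Under iron limitation 34 of 40 genes of the iron uptake and deficiency regulon rose and 1 fell, against 36 and 1 adjusted over the list alone. IRT1 went from 7.74 ± 0.20 to 10.06 ± 0.07 log2 units (SD, n = 4, limma adjusted p = 2.69e-08) and FRO2 from 10.96 ± 0.18 to 12.75 ± 0.10. The transcription factor genes BHLH100 and BHLH39 (AT3G56980) rose 42.8-fold and 18.6-fold, and FIT, their partner, 2.06-fold. IMA3 (AT2G30766) rose 45.4-fold, ORG1 (AT5G53450) 11.2-fold and the reductase gene FRO3 (AT1G23020) 8.07-fold, and IMA1 (AT1G47400) and IRT2 (AT4G19680) had log2 changes of 4.59 and 3.98. The member that fell was the proton pump gene AHA2 (log2 change -0.55), named after its value was seen. The list had a median log2 change of 2.21 (camera adjusted p = 1.08e-27, or adjusted p = 0.00599 with an estimated correlation).

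Iron storage genes had 6 of 11 members lower, 6 also adjusted over the list alone. The ferritin genes FER3 (AT3G56090), FER4 (AT2G40300) and FER1 had log2 changes of -1.68, -1.14 and -1.01, and VTL1 (AT1G21140) had -1.49. The list test was close to the threshold (camera adjusted p = 0.0485, or adjusted p = 0.278 with an estimated correlation). It was not past it without control replicate 2 or 4 or iron replicate 3 or 4 (adjusted p from 0.0578 to 0.0681), nor with the 8 arrays of the comparison alone (0.0806), among loci in the gene table (0.0509) or among probe sets above the median level (0.12). Other large rises were AT1G12030 and AT1G13609, with log2 changes of 6.08 and 5.96, CGLD27 (AT5G67370), with 5.63, AT5G25840, with 5.21, AT2G14247, with 5.21, and AT2G41730, with 5.14. The largest falls were AT1G52820, with a log2 change of -5.35, AT4G11190, with -4.03, and UMAMIT17 (AT4G08300), of an amino acid transporter family, with -3.98. XTH7 (AT4G37800), a xyloglucan-modifying enzyme gene, UMAMIT35 (AT1G60050) and AT4G35160 had -3.92, -3.90 and -3.69. AT4G12510 and AT4G12520, neighbouring loci whose probes could not be checked for overlap, had -3.96 and -3.57.

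Under iron limitation glucosinolate synthesis had 23 of 29 members lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 1.48e-07, or adjusted p = 0.248 with an estimated correlation). CYP79B3 and CYP83A1 (AT4G13770) fell 3.56-fold and 3.28-fold, and the chain elongation genes IPMI2 (AT2G43100) and IIL1 (AT4G13430) had log2 changes of -1.36 and -1.14. Sulfate transport and assimilation had 16 of 34 lower and 5 higher, against 16 and 6 adjusted over the list alone (camera adjusted p = 0.00804, or adjusted p = 0.198 with an estimated correlation). The sulfite reductase gene SIR (AT5G04590) fell from 11.30 ± 0.03 to 9.74 ± 0.20 log2 units (n = 4, limma adjusted p = 2.35e-08). The glutathione synthesis gene GSH1 (AT4G23100) and OASA1 (AT4G14880) were 1.94-fold and 1.81-fold lower and SERAT3;1 2.00-fold higher. Of the 12 sulfur deficiency markers 2 were lower, APR3 and LSU4 (log2 change -0.66, chosen after its value was seen), against 1 when adjusted over the list alone, and none was higher (limma, camera adjusted p = 0.605). SULTR1;1, SULTR1;2, SDI1 and LSU1 had log2 changes of -0.29, 0.00, 0.02 and 0.17, none past the threshold. APR3 had -0.68 (limma adjusted p = 0.0494), which was not past the threshold without control replicate 3 or 4 or iron replicate 1, 2 or 4 (adjusted p up to 0.158), with array weights (0.0574) or with eBayes with trend and robust (0.0725).

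Carbon starvation genes, which rise when sugars run low, had 8 of 9 members higher and 9 when adjusted over the list alone. SEN1 rose from 7.47 ± 0.99 to 10.96 ± 0.11 log2 units (n = 4, limma adjusted p = 3.63e-06), BCAT2 (AT1G10070), of branched-chain amino acid breakdown, 8.97-fold, the asparagine synthetase gene ASN1 (AT3G47340) 2.96-fold, and MCCA (AT1G03090) by 1.85 on the log2 scale. The list gave a camera adjusted p = 3.46e-06, or an adjusted p = 0.198 with an estimated correlation. All 10 cell division genes fell, also when adjusted over the list alone, with PCNA1 (AT1G07370) 3.00-fold, MCM2 2.02-fold and PCNA2 (AT2G29570) 1.95-fold lower (camera adjusted p = 2.19e-06, or adjusted p = 0.0672 with an estimated correlation). Nitrogen genes had 12 of 20 lower and 3 higher, against 13 and 3 adjusted over the list alone (camera adjusted p = 0.0074, or adjusted p = 0.0672 with an estimated correlation). NRT1.1, the nitrite reductase gene NIR1 (AT2G15620) and NIA1 fell 6.49-fold, 4.24-fold and 3.19-fold, while NPF7.2 (AT4G21680), which unloads nitrate from the xylem, rose by 3.44 on the log2 scale. HAK5 rose 2.69-fold and KUP3 fell 1.49-fold among the potassium genes, of which 6 of 34 were higher and 14 lower, against 7 and 16 adjusted over the list alone (camera adjusted p = 0.0806). AKT1 and SKOR had log2 changes of 0.12 and -0.29, not past the threshold.

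Xylem secondary wall markers had 5 of 6 members lower, 5 also adjusted over the list alone, with CESA8 (AT4G18780) at -0.90 and XCP1 at -0.70 on the log2 scale (camera adjusted p = 0.00642, or adjusted p = 0.198 with an estimated correlation). Endodermis and suberin markers had 5 of 14 lower, 5 also adjusted over the list alone, with FAR4 (AT3G44540) at -0.77 and CYP86A1 (AT5G58860) at -0.72 (camera adjusted p = 0.0433, or adjusted p = 0.278 with an estimated correlation). That list was not past the threshold without control replicate 2 (0.0584) or 3 (0.0539), without iron replicate 4 (0.0789), with the 8 arrays alone (0.0559), or among probe sets above the median level (0.0969). Hypoxia genes had 1 of 12 higher and 4 lower, also when adjusted over the list alone (camera adjusted p = 0.119), with SAD6 4.40-fold lower and ADH1 at a log2 change of -0.16, the latter not past the threshold and given after its value was seen. In all, 11141 probe sets were called, 5550 higher and 5591 lower, with 922 and 1066 at least 2-fold.

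**Figure D3:**
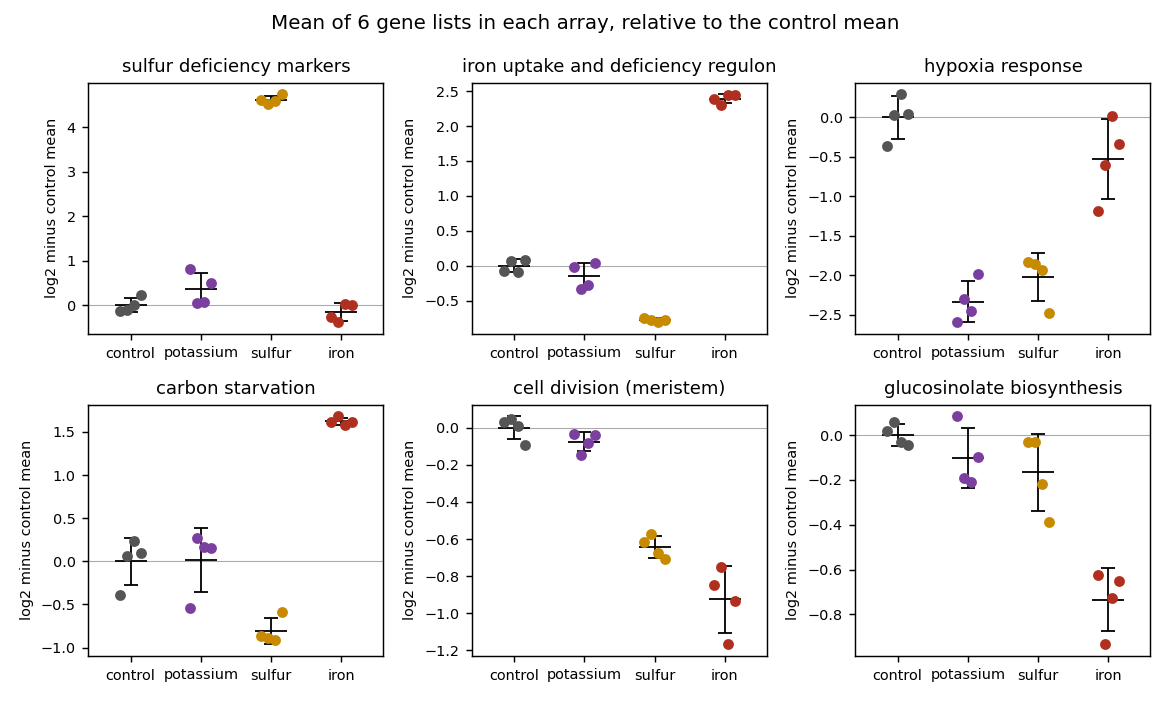
Mean log2 level of each of 6 gene lists in each array, minus the mean of the control arrays (vertical axes), for the 4 groups (horizontal axes), with 1 point per array and the mean ± SD as bars. Hypoxia genes average -2.33 under potassium, -2.02 under sulfur and -0.53 under iron limitation, and the sulfur deficiency markers stand apart under sulfur limitation.

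Compared directly, sulfur and potassium limited roots differed at 7985 probe sets, 3796 higher and 4189 lower under sulfur limitation (limma). SDI1 was 83.4-fold higher and LSU1 by 6.34 on the log2 scale, SULTR1;1 17.6-fold and APR3 7.18-fold higher, and SULTR1;2 1.93-fold higher under sulfur limitation. The difference of LSU1 is not exact, since its mean under potassium limitation was 2.12 log2 units, far below the array median of 5.62. HAK5 and IRT1 were 16.4-fold and 9.94-fold lower, FRO2 had a log2 difference of -3.70, SKOR 5.17-fold lower and AKT1 1.37-fold lower. BHLH39 and FER1 were 1.72-fold and 1.51-fold higher (limma adjusted p = 0.00627 and 0.0392), FIT 1.29-fold lower (limma adjusted p = 0.0432), and KUP3 differed by -0.13 on the log2 scale (limma adjusted p = 0.337). The call of FIT was lost with array weights (0.0641) and with the 8 arrays alone (0.0683). It was also lost without potassium replicate 1, 3 or 4 and without sulfur replicate 1, 2 or 4 (adjusted p up to 0.14). That of FER1 was lost without potassium replicate 2, 3 or 4 and without any 1 of the sulfur replicates (adjusted p up to 0.111). Of the 12 sulfur deficiency markers all were higher, also adjusted over the list alone (camera adjusted p = 1.44e-20, or adjusted p = 0.00406 with an estimated correlation). Of 34 potassium genes 17 were lower and 3 higher, against 18 and 3 adjusted over the list alone (camera adjusted p = 1.59e-05, or adjusted p = 0.0147 with an estimated correlation). The myb-related gene RL3 (AT4G36570) was lower than control under potassium limitation (log2 change -1.70) and higher under sulfur limitation (3.18), and the defensin-like gene PDF2.1 (AT2G02120) was higher (1.84) and lower (-1.69).

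Iron and sulfur limited roots differed at 9945 probe sets, 4984 higher and 4961 lower under iron limitation (limma). FRO2 and IRT1 were 51.5-fold and 50.3-fold higher under iron limitation, BHLH39 19.3-fold, SKOR 4.35-fold, HAK5 3.71-fold, FIT 2.77-fold and AKT1 1.34-fold. SDI1, LSU1, APR3 and SULTR1;1 were 207.3-fold, 68.9-fold, 16.6-fold and 11.8-fold lower, FER1 7.03-fold, while SULTR1;2 and KUP3 had log2 differences of -1.14 and -0.42. The fold change of LSU1 is not exact, since its mean under iron limitation was 2.35 log2 units, far below the array median of 5.62. The means of IRT1 under sulfur limitation (4.41) and SDI1 under iron limitation (4.32) also lay below that median, so their fold changes may be compressed. Of the 40 iron uptake and deficiency genes 38 were higher and none lower, with 39 higher adjusted over the list alone (camera adjusted p = 2.66e-40, or adjusted p = 0.00206 with an estimated correlation). All 9 carbon starvation genes were higher, also adjusted over the list alone (camera adjusted p = 1.61e-09, or adjusted p = 0.101 with an estimated correlation). Lower than control under sulfur and higher under iron limitation were AT5G38820 (log2 changes -2.99 and 2.78), BHLH100 (-2.72 and 5.42) and S8H (-3.58 and 2.45).

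Iron and potassium limited roots differed at 10523 probe sets, 5196 higher and 5327 lower under iron limitation (limma). BHLH39, IRT1, FRO2 and FIT were 33.3-fold, 5.06-fold, 3.98-fold and 2.15-fold higher and SULTR1;1 1.49-fold higher under iron limitation. FER1, HAK5, APR3 and KUP3 had log2 differences of -2.22, -2.14, -1.21 and -0.55. SDI1 was 2.49-fold lower (limma adjusted p = 0.0193), a call lost with the 8 arrays alone (adjusted p = 0.07) and without potassium replicate 1 (0.0715) or 4 (0.0632) or iron replicate 2 (0.0699). LSU1, SULTR1;2, SKOR and AKT1 differed by 0.23, -0.19, -0.25 and -0.04 on the log2 scale, not past the threshold. Hypoxia genes were higher under iron than under potassium limitation, 11 of 12, with 11 also adjusted over the list alone (median log2 difference 1.74, camera adjusted p = 6.07e-07, or adjusted p = 0.16 with an estimated correlation). Lower than control under potassium and higher under iron limitation were AT2G14247 (log2 changes -2.03 and 5.21), BHLH100 (-1.50 and 5.42) and AT5G05250 (-1.43 and 2.98).

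Called in all 3 limitations against control were 471 probe sets, 133 higher in all, 177 lower in all and 161 of mixed direction. The 3 comparisons share the control arrays, and no number for independent lists or split controls was computed for this count. SAD6, PDC1, AT4G33560 and AT2G43890 were lower in all 3, and GI (AT1G22770), a gene of the circadian clock, was higher in all 3, by 1.88, 3.30 and 1.45 on the log2 scale under potassium, sulfur and iron limitation. PDC1 under iron limitation (log2 change -1.36, limma adjusted p = 0.0321) was not past the threshold without control replicate 2, 3 or 4 or iron replicate 1 or 2 (adjusted p up to 0.116), nor with eBayes with trend and robust (0.0589). AT1G12030 was among the 8 largest rises under both sulfur and iron limitation.

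Sulfur and iron limitation shared 5014 calls, 1756 higher in both, 2442 lower in both and 816 opposite, against 767, 852 and 1617.6 for independent lists. With the 4 controls split 2 and 2, in all 6 ways, they shared between 2470 and 2761 calls in the same direction and between 471 and 592 in opposite directions. Potassium and sulfur limitation shared 450 calls in the same direction and 179 in opposite directions, against 157.4 and 156.3 for independent lists, and between 136 and 214, and 56 and 90, with split controls. Potassium and iron limitation shared 611 and 147, against 216.3 and 216.2, and between 191 and 331, and 31 and 78, with split controls. The numbers for independent lists hold for the fits with all 4 controls. None was taken for split controls, where each comparison has 2 controls, so the counts with split controls cannot be set against them. In 100 simulations of unchanged groups sharing the controls, at most 2 calls in the same direction were shared by any pair. Such groups hold no true changes. This count therefore does not show how many shared calls the common controls add where many probe sets are called. The covariance of the log2 changes across probe sets, which are not independent replicates, was 0.0961 for sulfur and iron, 0.0306 for potassium and sulfur and 0.0365 for potassium and iron. The simulations gave 0.0122, 0.0117 and 0.0109. The correlations were 0.359, 0.261 and 0.248, where the simulations gave 0.491, 0.474 and 0.450. In the simulated groups the shared controls alone set the correlation. True changes add to the spread of the observed log2 changes, so the observed and simulated correlations cannot be set against each other. The shared counts with potassium limitation moved by over 1.5 times without some arrays: in the same direction to 292 with sulfur and 399 with iron without control replicate 3, and to 396 with iron without potassium replicate 4. In opposite directions the count with sulfur was 119, 116, 109 and 119 without control replicates 1 to 4 and 113 without potassium replicate 4. With iron it was 82, 80 and 94 without control replicates 2, 3 and 4 and 95 without potassium replicate 4.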

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

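For each named gene and each group of 4 arrays, the gap between the array at either end and its nearest neighbour was divided by the range of the 4 values. The ratio was high in 35 of 572 groups of values from 143 genes, where chance gives about 28.6, so single cases carry little weight. Of these, 14 were in sulfur, 10 in iron, 7 in control and 4 in potassium arrays. The design has 1 tissue and 1 time point, so no effects were compared between tissues or times.

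Sulfur replicate 4 was the array apart in 7 cases, and it also lay farthest from its group mean over all probe sets (root mean square deviation 0.242). The ratios were 0.925 for ADH1 (7.66 against a mean of 8.45 log2 units in the other 3), 0.893 for PCO2 (6.17 against 7.06), 0.909 for BGLU28 (10.55 against 9.15), 0.87 for AT1G67865, 0.901 for CASP1, 0.832 for GSH1 and 0.91 for MCM2. Sulfur replicate 2 stood apart for VTL1 (0.949), MTP1 (0.863), VND7 (0.863), AT5G25840 (0.849) and IRT1 (0.843). Sulfur replicate 1 stood apart for NIP2;1 (0.904) and FER4 (0.833).

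Iron replicate 2 stood apart for VTL5 (0.933, 8.56 against 7.59), AT1G13609 (0.928), JAZ2 (0.92), PCNA2 (0.883), FER1 (0.851, 7.69 against 6.49) and SHM7 (0.833). Iron replicate 1 stood apart for AT5G10040 (0.863), where it was at 3.64 and the other 3 averaged 8.42 log2 units, for NRT2.4 (0.877) and for BCAT2 (0.836). Iron replicate 4 stood apart for BGLU28 (0.98, 4.19 against 3.42).

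In the control, replicate 4 stood apart for PCNA2 (0.982) and MYB122 (0.907), replicate 3 for S8H (0.981) and GGP1 (0.83), replicate 2 for PDF2.1 (0.962) and IMA3 (0.875), and replicate 1 for GI (0.915, 5.65 against 6.57). Among the potassium arrays, replicate 4 stood apart for ZIP2 (0.942) and PDC1 (0.935), and replicate 1 for JAZ2 (0.909) and ORG1 (0.83).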

How the results depend on the processing

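Overlaps without 1 array and list tests with centring, array weights, loci in the gene table or 8 arrays were added after seeing the data; quantile normalization and centring move almost nothing in values already made equal between arrays. No result changed direction past the threshold. Of 212 calls for named genes 196 were kept without any 1 array and 16 were lost, and 14 others were gained. Under the other settings 12 were lost and 17 gained. Many of these genes were named for large changes or small adjusted p in the same data, so the share kept does not hold for calls in general. Of 26 list tests 22 were kept without any 1 array and 4 were lost, and 10 others were gained without at least 1 array.

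With array weights the potassium count was 1732 (860 higher, 872 lower); the cause was not tested. Among probe sets above the median level, where fewer were tested, calls of at least 2-fold numbered 117 instead of 177 for potassium, 692 instead of 1070 for sulfur against potassium and 1224 instead of 1874 for iron against sulfur. Opposite calls numbered 276 instead of 179 for potassium and sulfur and 226 instead of 147 for potassium and iron, and the cause was not tested. With an estimated correlation 6 list tests passed. With split controls, which leave fewer samples, the median numbers of calls shared in the same and in opposite directions were 145 and 65 for potassium and sulfur, 216 and 56.5 for potassium and iron, and 2561.5 and 513 for sulfur and iron.

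Leaving out each array gave 681 to 1031 calls for potassium limitation (306 to 529 higher, 373 to 502 lower). Shared calls with potassium ranged from 292 to 508 (same) and 109 to 213 (opposite) for sulfur and from 396 to 623 and 80 to 142 for iron.

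Replicate numbers gave no clear pairing of the arrays: correlations of same-numbered deviations ran from -0.081 to 0.19. Their median was 0.007, against 0.006 for other numbers. Of 16 arrays 7 matched their own number best, and the number expected by chance was not computed. With the replicate block the counts were 1024 (potassium), 7816 (sulfur), 10874 (iron), 7757 (sulfur against potassium), 9702 (iron against sulfur) and 10230 (iron against potassium), with 25 list tests passing. Low values near background limit what can be seen in dim genes.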

Other observations

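Further changes in the lists are given here, mostly under iron limitation. The genes were chosen after their values were seen, apart from NPF7.2 under iron limitation, which the rule named. Of 9 root hair markers 5 were lower and 1 was higher (camera adjusted p = 0.0881): PRP3 and LRX1 fell by 1.54 and 1.22 on the log2 scale, and RSL4, a transcription factor gene that drives root hair growth, rose by 2.36. Of 11 salicylate and defence genes 4 rose (camera adjusted p = 0.0838), among them CYP71A13, of camalexin synthesis, by 2.75 and CBP60G by 1.48. Of 11 ethylene genes 4 were higher and 1 was lower, also when adjusted over the list alone (camera adjusted p = 0.287), and ACS7, a gene of ethylene precursor synthesis, rose by 2.83. None of the 8 flavonoid genes was called in any limitation (limma), with camera adjusted p = 0.109, 0.751 and 0.549 for potassium, sulfur and iron. The nitrate transporter gene NPF7.3, which loads the xylem, fell by 1.47 under sulfur and 2.02 under iron limitation, while NPF7.2 rose by 2.78 and 3.44.

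The tests below were chosen after the results were seen, except the counts over other splits of the arrays and the difference between evening and morning clock genes as a test of both limitations together, which were chosen before their results.

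Hypoxia response genes were lower under potassium and sulfur limitation than in the control. A single control array is excluded as the source: whichever was left out, the median log2 change of the list stayed at -1.93 or below in both comparisons. A feature of the control roots alone is argued against by the comparison of iron with potassium limitation, without the controls, where the median difference was 1.74 (11 of 12 genes higher, camera adjusted p = 6.07e-07, or adjusted p = 0.16 with an estimated correlation). Different oxygen supply of the growth vessels cannot be told apart from the limitations: the range of the group means was 4.62 times the largest SD within a group, and the labels used here name no vessel or aeration for any sample. The biological explanation, that the limitations themselves lower these genes, stays open and was not tested.

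Of the iron uptake and deficiency regulon 23 of 40 genes were lower under sulfur limitation. No single array accounts for this, since the median log2 change stayed at -0.41 or below without any 1 of the 8, and the control roots alone are argued against by sulfur against potassium limitation, where the median difference was -0.33 (camera adjusted p = 3.39e-05, or adjusted p = 0.16 with an estimated correlation). A loss of root hair cells lowers the root hair markers most, if these are made there alone and keep their level per cell. This premise was not tested, and under iron limitation the markers moved both ways. Under sulfur limitation their mean log2 change was -0.161 ± 0.111 (SE), while the mean of all 40 genes was -0.781. The difference of -0.619 ± 0.133 (SE) would argue against such a loss as the whole source only on that premise. A loss of root hair cells, as the whole source or a share of it, stays open. An effect of sulfur limitation itself stays open, untested, as a hypothesis found on the same data.

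GI was higher under potassium limitation (1.88) and RVE2, chosen after its value was seen like CCA1 and LHY below, lower under sulfur limitation (-3.05). No single array accounts for it, since GI stayed at 1.66 or above and RVE2 at -2.92 or below without any 1 of the 8 arrays. Harvest at different times of day as the source of both is argued against by the bound set beforehand, a difference between 5 evening and 5 morning clock genes, without GI and RVE2, within 0.5 of 0 in either limitation: it was -0.026 ± 0.148 (SE, percentile 42 of random gene groups) under potassium limitation. As 3 of the 5 evening genes lie below the median level, where RMA compresses changes, it was also taken, after this was seen, over the 2 evening and 5 morning genes above that level, and was 0.178 ± 0.109, with CCA1 and LHY at -0.11 and 0.07. Under sulfur limitation the differences were 0.857 ± 0.134 (percentile 99.94) and 1.57 ± 0.112. Under iron limitation they were 0.136 ± 0.226 (percentile 70.54) and 0.81 ± 0.201. For RVE2 under sulfur limitation a harvest at another time, which the labels do not give, therefore cannot be told apart from the limitation. The limitation's own effect stays open, untested. GI also rose under sulfur and iron limitation, against the same controls. The same limit on harvest time holds for GI under sulfur limitation. A feature of the control roots alone was not tested for GI and stays open.

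Chance assignment of arrays to groups was examined with the 35 splits of the 8 arrays in each of the 6 comparisons. In each comparison 1 of the 35 splits, the real one, gave as many calls. This is the smallest share that 35 splits can give, so chance assignment is argued against to that extent and is not excluded. Every other split mixes the compared groups on each side, and the differences between these groups then add to the spread. The counts of the other splits are therefore not a level given by chance. The highest count of any other split was 3 against 1080 for potassium, 4 against 8082 for sulfur and 20 against 11141 for iron limitation compared with control. For sulfur against potassium, iron against sulfur and iron against potassium it was 81 against 7985, 1 against 9945 and 1 against 10523.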
